A study of Mus musculus with 6 samples.

How the data were processed

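Whole kidneys of mice 8 weeks old were frozen and RNA was extracted with Trizol, and sequencing libraries were made from total RNA with the Illumina TruSeq kit, per the labels' protocols. The labels place 3 libraries in the wild-type group and 3 in the group with the R26NICD2 allele and Pax8-Cre, here NICD2_Pax8. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical.

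The deposited table held 1 row per gene, 23873 in all. Its columns were FPKM per library, made by the authors and named so per the file headers. No scaling for library composition is named. The authors also gave the mean FPKM of each group, log2 fold changes for the group comparison and for 3 pairs of single libraries, and p-values and q-values, which per the file headers came from DESeq2 for the groups and from a Poisson test for the pairs. The single pair columns were not used here. Positions, gene lengths and other annotation columns were given by the authors beside these values. The submitters' processing notes name Bowtie 0.12.2 and the build mm8. The positions in the file are not those of that build: of 22002 gene identifiers matched to the RefSeq annotation of GRCm38, 19406 (88.2%) had the same start and end, so coordinates are given as in the file and read as GRCm38. The tool that counted the fragments and the version of the annotation are not given in the sources used here. There were 0 further columns of single libraries.

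Of the rows, 4370 had no values in any library and were left out, and 19503 remained. The row named NOTCH2 in capitals carries no position and was kept. The test planned before the data were examined was the edgeR quasi-likelihood test on counts, with a fallback for a file without counts. Because the file held FPKM, the fallback was used: limma 3.58.1 with a mean-variance trend in R 4.3.3 on log2(FPKM + 1), with genes kept at 1 FPKM or more in at least 3 libraries, which left 13500. The test was two-sided with genotype as the only term, and Benjamini-Hochberg adjusted p under 0.05 was called. Standard errors are those of limma. Errors on FPKM are SD over 3 libraries. Folds are ratios of group mean FPKM unless given as log2 fold changes, which are on the log2(FPKM + 1) scale.

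Before the data were examined, 20 study lists and 7 control lists of genes were fixed. Some genes stand in more than 1 list, so the lists are not independent. Among them are Sox9 and Cdkn1a (Notch targets and tubular injury), Notch3 (both Notch lists) and Vcam1 (cytokines and tubular injury). Each list was tested with camera from limma with a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, and adjusted over the lists of its kind. Members were counted as rising, falling or not passing over all genes tested and adjusted over the list alone. Members under the filter were not measured. Xist was not analysed here. The named genes were fixed by rule before the data were examined: the 6 largest rises and the 6 largest falls among called genes whose 3 libraries of 1 group all lie above the 3 of the other and whose mean is at least 1 FPKM, leaving out predicted genes; Notch2, Hes1, Hey1, Heyl, Pkd1, Pkd2 and Pkhd1; the 2 members of each study list with the smallest p; and the most abundant member of each control list. Other list members named as examples were chosen after their values were seen. Some results that these rules select are not reported here.

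Depth is not in the file. It was estimated from genes with 1 transcript of 500 to 1500 bases, whose low FPKM values times an effective length should be whole multiples of the value of 1 fragment. The step and the length offset that gave the sharpest steps were taken, and 71.8% to 78.2% of values up to 8 fragments then lay within 0.15 of a whole number. For a step fixed in advance 30.0% would by chance. The step and offset were chosen on the same values, which raises the chance share, and that share was not computed. The estimate serves only to give the precision, and no test of counts was made from it. In simulated data on 13500 genes with the wild-type means and the residual spread of these libraries, the test recovered 63% of 100 genes changed by log2 1 and 91% of 100 genes changed by log2 2, with 5.52% of calls false, and camera recovered 5 of 5 shifted lists with 0 false ones. Far fewer genes were changed in the simulation than were called in the data, so these shares do not give the recovery here. The simulated genes were drawn independently, so the result for camera does not test the preset correlation.

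Alternatives were pseudocounts of 0.1 and 5, no filter, quantile normalization, median-of-ratios scaling, upper quartile scaling, the replicate number as a block, each library left out in turn, an adjusted p of 0.01, and an absolute log2 fold change of at least 1. A filter of 10 FPKM and median-of-ratios scaling without wild-type replicate 1 were added after seeing the data. The upper quartile factors were rescaled to a geometric mean of 1 after a first version, which had multiplied all values by a constant, was found to shift the pseudocount. Folds of group means were also computed with each library left out in turn, after seeing the data; where 1 library moves a printed fold by more than 1.5 times, that fold or the values of the single libraries are given. Pathways in the authors' annotation column with 15 to 300 tested genes were tested with camera. Figures were drawn with matplotlib 3.10.9.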

Results

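RNA was sequenced from whole kidneys of mice 8 weeks old. There were 2 groups of 3 libraries. By its labels the first was wild type. The second, here NICD2_Pax8, carried a Cre-dependent allele at the Rosa26 locus that encodes the intracellular domain of Notch2, the part of this receptor that enters the nucleus and activates transcription without ligand, together with a Pax8 driver, which is active along the renal tubule epithelium. The titles and column names of the wild-type libraries begin with NICD and those of the second group with NICD_Pax, so the wild-type kidneys may have carried the allele without the driver, and the sources used here do not settle it. The labels name Pax8-Cre as the driver, whereas the series title names a Pax-rtTA driver, and which one was used is not settled by the sources used here. The title states the question as whether Notch2 activation drives the growth of cysts in the kidney. Expression was given as FPKM, and the depth estimated from the steps between low FPKM values was 14800000, 14900000 and 15000000 fragments in wild-type replicates 1 to 3 and 15900000, 16800000 and 17900000 in NICD2_Pax8 replicates 1 to 3. A value of 1 FPKM for a transcript with an effective length of 1 kb then rested on about 15 to 18 fragments.

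The transcripts named for the receptor and the driver were read first. A row named NOTCH2 in capitals, with no position or annotation in the file, stood at 2.13, 3.75 and 1.27 FPKM in the 3 wild-type libraries and at 500.5, 521 and 570 FPKM in the 3 NICD2_Pax8 libraries, a log2 fold change of 7.36 (SE 0.25, adjusted p = 1.57e-05). No source used here says what this row is, so it is not known to be the transgene. The row of the annotated gene Notch2 (gene 18129, chromosome 3, 98013538 to 98150367) rose from 5.08 ± 0.771 to 12.8 ± 0.625 FPKM (SD, n = 3 each; log2 fold change 1.19, SE 0.13, adjusted p = 3.72e-04). Pax8 itself (gene 18510), the transcription factor whose promoter names the driver, rose from 41.4 ± 5.38 to 95.0 ± 6.22 FPKM (SD, n = 3 each; adjusted p = 3.15e-04). Fragments of a transgene made of Notch2 sequence may count to the Notch2 row, and endogenous transcription was not separated from them. For all 3 rows the 3 libraries of each group did not overlap. After median-of-ratios scaling the log2 fold changes of NOTCH2, Notch2 and Pax8 were 7.06, 0.88 and 0.84.

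In the NICD2_Pax8 kidneys, most measured members of the lists of Notch targets, cell division, cytokines and tubular injury rose. Most members of the lists of proximal tubule, thick ascending limb, distal tubule, intercalated cells, podocytes, endothelium and fatty acid oxidation fell. These lists passed as sets with a preset correlation between genes, and 0 of the 20 study lists passed with an estimated correlation. Of 13500 genes tested, 8285 passed an adjusted p of 0.05, with 6095 higher and 2190 lower in NICD2_Pax8 kidneys (73.6% higher). On unscaled FPKM the 3 libraries of each group did not overlap for 6741 genes higher and 2533 lower. By chance alone 10% of genes would be separated, but this share ignores a shift common to all genes. An upward shift would add to the genes higher, and separation after scaling was not counted. The balance between the directions rested on the scaling: with median-of-ratios scaling 7346 genes passed, 3873 higher and 3473 lower (52.7% higher), and the median log2 fold change of all tested genes moved from 0.32 to 0.02. In the authors' deposited table, 8327 of 19439 genes passed a q of 0.05, with 4143 higher and 4184 lower, and 5997 genes passed both tests in the same direction with 0 in opposite directions. The 10 most abundant genes took 17.4% to 23.4% of summed FPKM in the wild-type libraries and 6.65% to 7.62% in the NICD2_Pax8 libraries, and their effect on the balance was not tested. Kap, an androgen-regulated proximal tubule protein, took 9.82%, 14.1% and 14.5% of summed FPKM in the wild-type libraries and 0.0116%, 0.783% and 0.14% in the NICD2_Pax8 libraries.

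The first principal component, with 82.7% of the variance, separated the groups. The second, with 9.03%, set wild-type replicate 1 apart. That library held adrenal transcripts, with Hsd3b1 at 1208 FPKM, Cyp21a1 at 906, Cyp11a1 at 626 and Star at 597, where the other 5 libraries held at most 1.37 FPKM of each. It also held the most fat transcripts, with Fabp4, a fatty acid carrier of adipocytes, at 2139 FPKM against 527 and 117 in wild-type replicates 2 and 3 and 45.5 to 159 in NICD2_Pax8. Without this library 8706 genes passed, 6644 higher and 2062 lower.

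**Figure D1:**
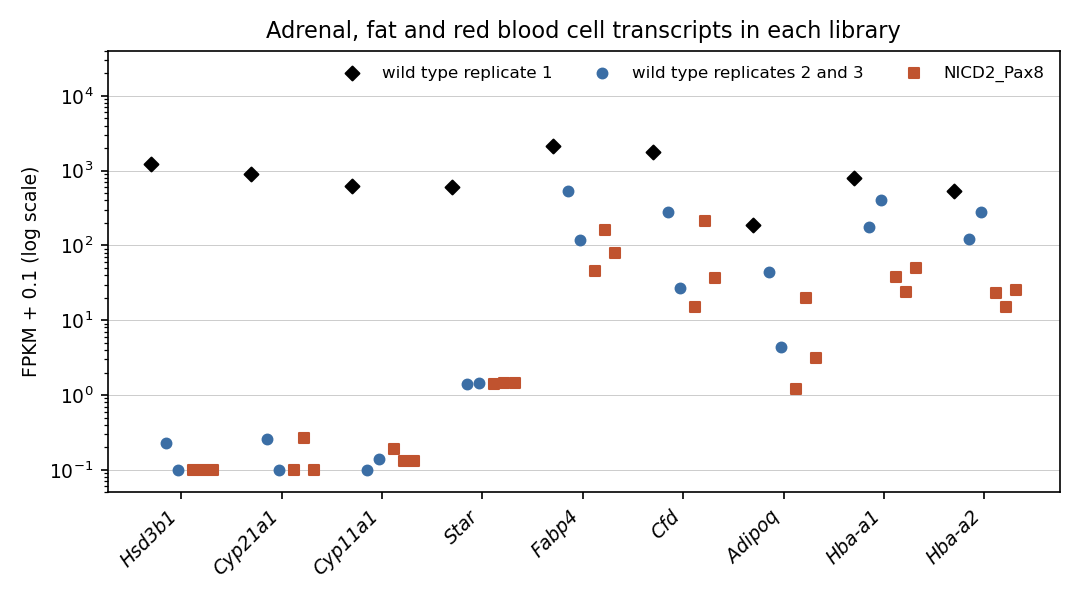
FPKM plus 0.1 on a log axis for 4 adrenal, 3 fat and 2 red blood cell genes, with 1 point per library. Black diamonds are wild-type replicate 1, blue circles wild-type replicates 2 and 3, and orange squares the 3 NICD2_Pax8 libraries; the 4 adrenal genes reach 597 to 1208 FPKM in wild-type replicate 1 alone.

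Notch target genes rose together. Heyl (gene 56198, chromosome 4, 123233556 to 123249870), a transcriptional repressor induced by Notch, rose from 1.78 ± 0.73 to 203.8 ± 12.3 FPKM, and Nrarp (gene 67122, chromosome 2, 25180758 to 25183339), a feedback regulator of the pathway, rose from 3.66 ± 1.89 to 498 ± 19.1 FPKM (SD, n = 3 each). Hes1 rose 4.74-fold in mean FPKM, Hey1 12.2-fold (20.3-fold without wild-type replicate 1) and Sox9, a regulator of tubule progenitors, 53.6-fold. All 12 measured members of the list of Notch targets rose, with the same count adjusted over the list alone (camera adjusted p = 1.67e-05; adjusted p = 0.244 with an estimated correlation). All 12 also rose after median-of-ratios scaling. Sox9 and Cdkn1a are also members of the list of tubular injury.

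Receptors, ligands and processing factors of the pathway moved unevenly. Jag1, a Notch ligand, rose from 3.24 ± 0.486 to 64.4 ± 8.29 FPKM and Notch1 from 3.6 ± 0.954 to 51.9 ± 0.933 FPKM (SD, n = 3 each). Notch3 rose 7.92-fold and the glycosyltransferase Lfng 4.14-fold in mean FPKM, while Notch4, a receptor of endothelium, fell 2.66-fold. Of 24 measured members 14 rose and 1 fell, and adjusted over the list alone 15 rose and 1 fell. The list as a set did not pass (camera adjusted p = 0.227; adjusted p = 0.609 with an estimated correlation), and after scaling 11 rose and 5 fell.

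**Figure D2:**
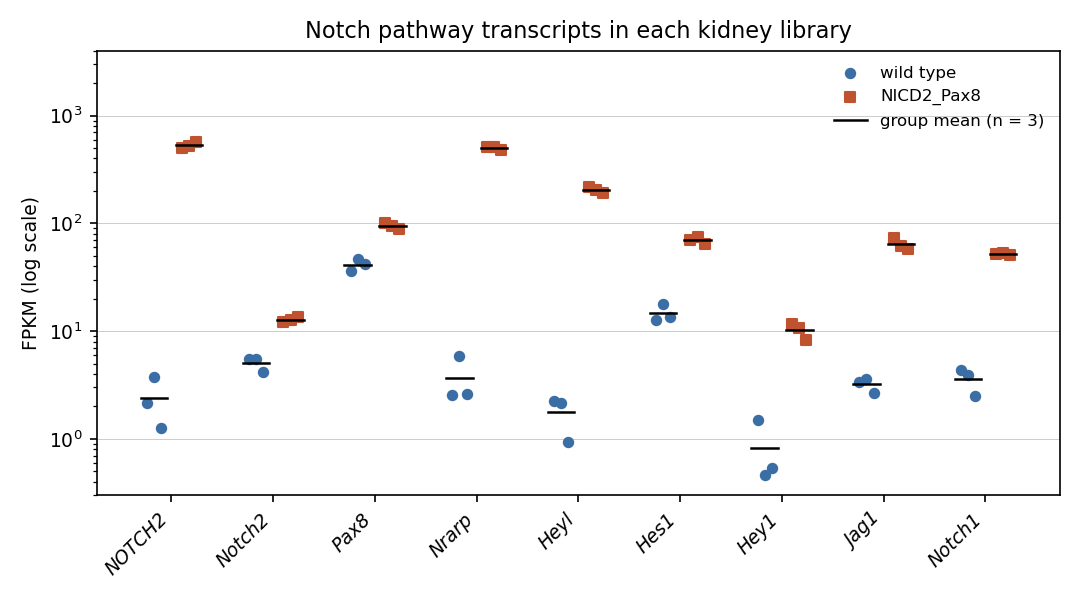
FPKM on a log axis of the NOTCH2 row, Notch2, Pax8 and 6 genes of the Notch pathway, with 1 point per library and a bar at the mean of each group (n = 3). Blue circles are wild type and orange squares NICD2_Pax8; for each of these 9 rows the 3 NICD2_Pax8 values lie above the 3 wild-type values.

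Among the 6 named genes with the largest rises, Clec18a, a lectin, went from 0.713 ± 0.55 to 185.5 ± 28 FPKM, and Cyp2f2, a cytochrome P450 best known from airway club cells, from 3.9 ± 1.44 to 548 ± 205 FPKM (SD, n = 3 each). The largest rise was listed under Vmn1r32 (gene 171188, chromosome 6, 66552177 to 66612568), from 1.35 ± 0.633 to 420.5 ± 138 FPKM with a log2 fold change of 7.47 (SE 0.27, adjusted p = 1.87e-05). Its model in the file includes transcripts under the authors' own identifiers beside the annotated vomeronasal receptor, so the signal may not belong to the receptor. The other members of this set were NOTCH2, Nrarp and Heyl.

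Most proximal tubule transcripts fell. Slc22a8 (gene 19879, chromosome 19, 8591254 to 8611835), an organic anion transporter, fell from 192.4 ± 33.4 to 3.98 ± 6.6 FPKM, and Miox, which begins the breakdown of inositol, from 1855 ± 410.4 to 46.4 ± 62.5 FPKM (SD, n = 3 each). Slc34a1, the phosphate cotransporter, fell 15.5-fold in mean FPKM (24.2-fold without NICD2_Pax8 replicate 2), and the 2 members with the smallest p, Slc17a3 and Dpep1, fell 12.1-fold and 14.9-fold. Of 22 measured markers 20 fell and 0 rose, with the same counts adjusted over the list alone and a median log2 fold change of -2.67 (camera adjusted p = 1.23e-12; adjusted p = 0.244 with an estimated correlation). The exceptions were Hnf4a, at 184.8 ± 28.5 against 122.9 ± 50.4 FPKM, and Slc4a4, at 107.9 ± 16.9 against 128.4 ± 17.9 FPKM (SD, n = 3 each). After scaling 21 fell.

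The 6 named genes with the largest falls in log2 fold change were abundant in the wild-type kidney. On the log2(FPKM + 1) scale only abundant transcripts can fall this far, so their abundance follows from the ranking. Outside this set, Cyp4a14 fell 53.8-fold in mean FPKM, or 611.8-fold without NICD2_Pax8 replicate 2. Kap (gene 16483, chromosome 6, 133849855 to 133853667) fell from 73285 ± 15627 to 1661 ± 2218 FPKM (SD, n = 3 each), a log2 fold change of -6.98 (SE 1.38, adjusted p = 0.00448). Akr1c21, a hydroxysteroid dehydrogenase, fell 41.2-fold, Inmt, a methyltransferase, 38.0-fold and Dnase1, a secreted nuclease, 48.1-fold in mean FPKM. Slc22a8 and Miox complete this set. NICD2_Pax8 replicate 2 kept the highest level of all 6 genes of this set and carries most of their NICD2_Pax8 means. Kap stood there at 4192 FPKM against 59.9 and 730.2 FPKM in replicates 1 and 3, Dnase1 at 21.2 against 0.48 and 1.07, Inmt at 57.1 against 0.57 and 5.09, and Akr1c21 at 64.4 against 0.88 and 7.51 FPKM.

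Of 10 measured markers of the thick ascending limb, 8 fell and 0 rose (camera adjusted p = 3.3e-05; adjusted p = 0.252 with an estimated correlation), with the same counts adjusted over the list alone. Egf fell 40.5-fold and Slc12a1, the salt cotransporter blocked by loop diuretics, 11.2-fold in mean FPKM. Umod, the most abundant marker of this segment, stood at 1118 ± 425.5 in wild type and 1346 ± 339 FPKM in NICD2_Pax8 (SD, n = 3 each; adjusted p = 0.455). Egf stood at 1.29, 22.3 and 2.47 FPKM in NICD2_Pax8 replicates 1 to 3, and without replicate 2 its fall was 187-fold. The members with the smallest p, Ptger3 and Cldn10, fell 5.09-fold and 3.51-fold.

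In the distal convoluted and connecting tubule list, 7 of 9 markers fell and 1 rose, and adjusted over the list alone 8 fell and 1 rose (camera adjusted p = 2.43e-05; adjusted p = 0.244 with an estimated correlation). Slc12a3, the thiazide-sensitive cotransporter, fell from 226.9 ± 14.8 to 32.2 ± 7.32 FPKM (SD, n = 3 each). Pvalb, read at 16.9 to 17.5 FPKM in wild type, stood at 0, 1.47 and 0 FPKM in NICD2_Pax8, and Calb1, another calcium-binding protein, fell from 163.8 ± 43.8 to 9.4 ± 6.68 FPKM (SD, n = 3 each), with 17.1 FPKM in NICD2_Pax8 replicate 2 against 5.14 and 5.95 FPKM. Wnk4, a kinase that regulates this salt transport, was the member that rose, 2.22-fold in mean FPKM.

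Markers of the 2 cell types of the collecting duct went different ways in their counts, and the difference between the lists was not tested. Among 15 intercalated cell markers 12 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.33e-08; adjusted p = 0.244 with an estimated correlation). Atp6v1g3 and Atp6v0d2, proton pump subunits, fell 20.3-fold and 10.3-fold, and Foxi1, the transcription factor of this cell type, 9.8-fold in mean FPKM, with Foxi1 at 3.27 FPKM in NICD2_Pax8 replicate 2 against 0.43 and 0.98 FPKM. Rhbg, an ammonia transporter, rose 1.63-fold, while Car2 stood at 251.1 ± 0.423 against 220.1 ± 36.6 FPKM (SD, n = 3 each). Of 12 principal cell markers 4 rose and 3 fell, with the same counts adjusted over the list alone, and after scaling 4 rose and 5 fell. The sodium channel subunits Scnn1g and Scnn1b rose 3.01-fold and 2.35-fold and the transcription factor Elf5 15.6-fold, or 26.4-fold without wild-type replicate 2. The water channels Aqp2 and Aqp3 fell 6.16-fold and 7.97-fold, or 9.88-fold and 12-fold without NICD2_Pax8 replicate 2. The principal cell list did not pass (camera adjusted p = 0.556; adjusted p = 0.664 with an estimated correlation), and its median of 0.14 differed in sign from its mean of -0.01 and from the test, whose direction was down.

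Most podocyte and endothelial markers fell. Nphs1, the podocyte protein nephrin, fell from 5.74 ± 0.44 to 1.17 ± 0.302 FPKM (SD, n = 3 each), and Cdkn1c 3.7-fold. Of 10 podocyte markers 8 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.22e-04; adjusted p = 0.244 with an estimated correlation). Synpo, an actin-binding protein, rose 2.9-fold in mean FPKM. With median-of-ratios scaling or with quantile normalization 8 podocyte markers fell and 1 rose. Tek and Emcn of the endothelium fell 3.49-fold and 2.48-fold, and 9 of 11 endothelial markers fell with 0 rising, the same counts as adjusted over the list alone (camera adjusted p = 8.38e-07; adjusted p = 0.244 with an estimated correlation).

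Matrix genes rose, and markers of fibroblasts, pericytes and smooth muscle went both ways. Acta2, smooth muscle actin, rose from 29.3 ± 9.23 to 136.7 ± 21.2 FPKM (SD, n = 3 each) and Cspg4, a pericyte marker, 2.64-fold. Dcn and Pdgfra fell 3.51-fold and 2.39-fold, and Dcn was highest in wild-type replicate 1, at 134.3 FPKM against 68.8 and 59.5 FPKM in the others. In this list 5 of 12 rose and 2 fell, with the same counts adjusted over the list alone; 4 rose and 3 fell after median-of-ratios scaling, and 3 rose and 3 fell with quantile normalization. As a whole the set did not pass (camera adjusted p = 0.924; adjusted p = 0.965 with an estimated correlation; the median of 0.31 and mean of 0.35 were positive and the direction of the test was down). Of 24 matrix genes 17 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00332; adjusted p = 0.592 with an estimated correlation). Tgfb2, a growth factor, rose 9.95-fold and the basement membrane collagen Col4a1 3.91-fold in mean FPKM. After scaling 16 matrix genes rose and 2, Col6a1 and Col6a2, fell, and without wild-type replicate 3 also 2 fell. With the added scaling without wild-type replicate 1, 1 fell. Leaving out that library moved the unscaled fall of Col6a1 from 2.09-fold to 1.41-fold and that of Col6a2 from 1.38-fold to 1.11-fold.

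Inflammatory and injury transcripts rose. Spp1, osteopontin, rose from 562.4 ± 123 to 10658 ± 2296 FPKM (SD, n = 3 each), and Lcn2, a marker of tubular injury, from 3.35 ± 1.68 to 218.4 ± 145.1 FPKM (SD, n = 3 each). Havcr1, another injury marker, rose 9.14-fold, and the keratins Krt19 and Krt18 rose 32.6-fold and 21.3-fold in mean FPKM. Leaving out 1 library moved the fold of Krt19 to between 20.9 and 60.9. In the list of tubular injury and dedifferentiation 19 of 20 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.3e-05; adjusted p = 0.252 with an estimated correlation). Ccl2, a monocyte attractant, rose 77.2-fold (166.7-fold without wild-type replicate 1), and the adhesion molecules Icam1 and Vcam1 9.42-fold and 9.07-fold. In the cytokine and NF-kB list 18 of 19 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 7.58e-06; adjusted p = 0.252 with an estimated correlation).

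Of 17 macrophage and dendritic cell markers 14 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.00989; adjusted p = 0.609 with an estimated correlation). Cd14 rose 10.4-fold and Cd74, the invariant chain of antigen presentation, from 279.2 ± 55.2 to 1113 ± 199 FPKM (SD, n = 3 each). Wild-type replicate 1 had more Lyz2 than wild-type replicates 2 and 3, at 109 FPKM against 27.1 and 18.7 FPKM, but less Csf1r, at 11.45 against 20.6 and 17.3 FPKM; without this library 16 of the 17 rose. Of 13 lymphocyte markers 5 were measured and 3 rose, the same count as adjusted over the list alone, among them Cd8a, 8.49-fold, and Cd52, 2.42-fold or 4.06-fold without wild-type replicate 1; that list did not pass (camera adjusted p = 0.412; adjusted p = 0.664 with an estimated correlation). The count fell to 2 after scaling, where Cd3g did not pass (adjusted p = 0.0736), and to 1 when any of 4 of the 6 libraries was left out, among the lost calls that of Cd52.

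Genes of cell division rose throughout their list. Mcm3 and Mcm5, subunits of the replicative helicase, rose from 2.55 ± 0.566 to 46.8 ± 5.7 FPKM and from 2.15 ± 0.684 to 44.4 ± 6.7 FPKM (SD, n = 3 each). Mki67, a proliferation marker, rose 11.7-fold and Top2a 19.6-fold in mean FPKM, or 20.1-fold and 36.8-fold without wild-type replicate 2. Ccnd1, which drives entry into the cycle but belongs to the list of Notch targets, rose from 77.6 ± 18.7 to 658.7 ± 62.5 FPKM (SD, n = 3 each). All 21 measured members of the list of cell division rose, also after scaling and adjusted over the list alone (camera adjusted p = 1.45e-07; adjusted p = 0.304 with an estimated correlation).

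**Figure D3:**
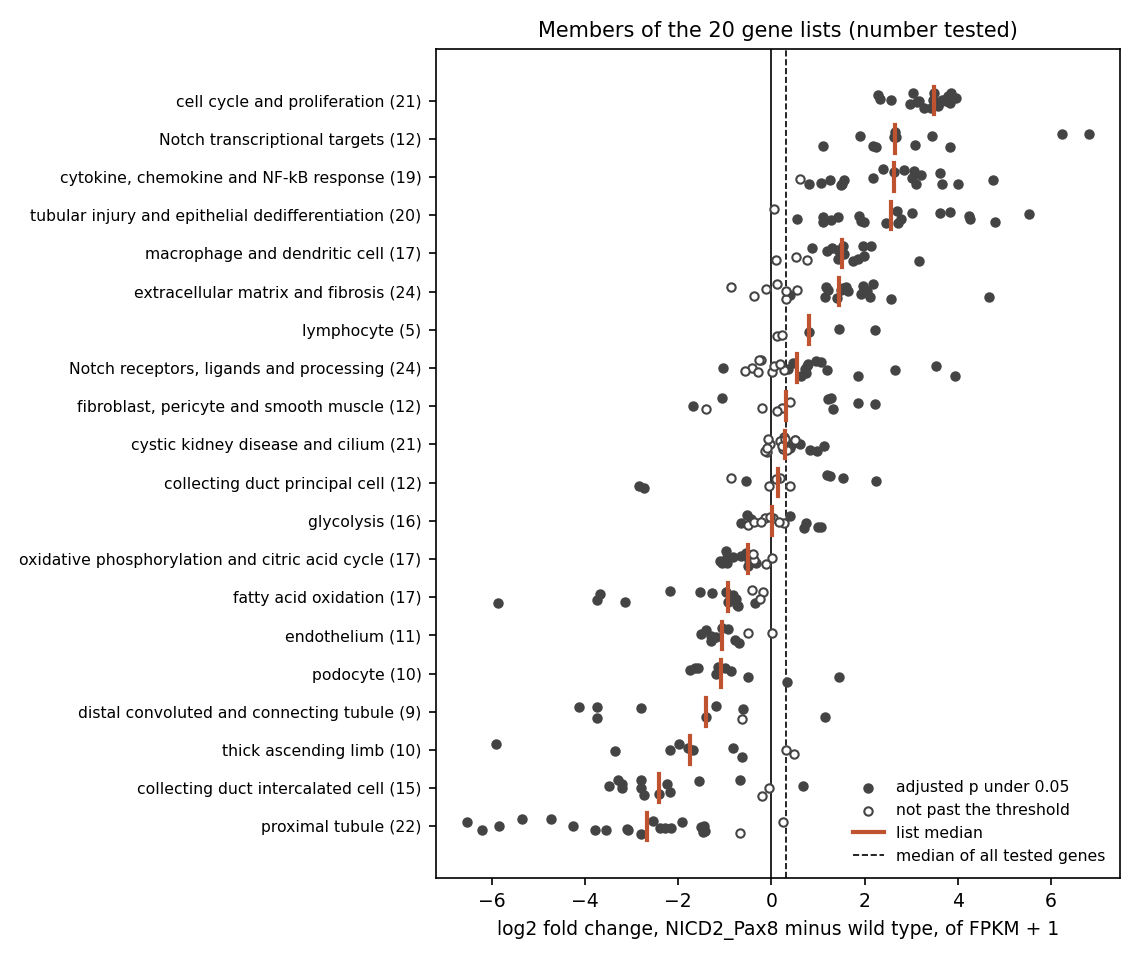
Log2 fold change of FPKM + 1, NICD2_Pax8 minus wild type, for each tested member of the 20 study lists, ordered by list median. Filled points passed the adjusted threshold, open points did not, orange bars are list medians, and the dashed line is the median of all tested genes at 0.32; medians run from -2.67 for proximal tubule to 3.49 for cell cycle.

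Fatty acid oxidation and mitochondrial genes fell. Acadm, a medium-chain acyl-CoA dehydrogenase, fell from 414.6 ± 69.1 to 90.6 ± 10.5 FPKM (SD, n = 3 each), and Cyp4a10, a fatty acid hydroxylase, fell 12.9-fold. The related Cyp4a14 fell to 0.16, 7.07 and 0.28 FPKM in NICD2_Pax8 replicates 1 to 3 from 115 to 148.1 FPKM in wild type. Of 17 genes of fatty acid oxidation 14 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.27e-09; adjusted p = 0.244 with an estimated correlation). Sdhb and Ndufs1, of the respiratory chain, fell 2.15-fold and 1.94-fold. In the list of oxidative phosphorylation and the citric acid cycle 13 of 17 fell and 0 rose, and adjusted over the list alone 15 fell (camera adjusted p = 5.76e-08; adjusted p = 0.244 with an estimated correlation). After scaling all 17 members of each of these lists fell. Of 16 glycolysis genes 5 rose and 3 fell, with the same counts adjusted over the list alone, and after scaling 2 rose and 5 fell; the list did not pass (camera adjusted p = 0.278; adjusted p = 0.642 with an estimated correlation; median 0.00, mean 0.10, direction of the test down). Pfkp rose 2.08-fold and Hk1 1.64-fold, and the call of Hk1 ended with scaling (log2 fold change 0.36, adjusted p = 0.105).

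The genes mutated in polycystic kidney disease did not pass the main test on unscaled FPKM. Pkd1 passed as lower after scaling, with quantile normalization and in the authors' test. Pkd1 stood at 4.45 ± 0.626 in wild type and 4.33 ± 0.312 FPKM in NICD2_Pax8 (SD, n = 3 each; adjusted p = 0.867), Pkd2 at 31.1 ± 5.24 and 28.7 ± 0.978 FPKM (adjusted p = 0.569), and Pkhd1 at 9.27 ± 2.59 and 11.01 ± 0.926 FPKM (adjusted p = 0.307). Relative to the median of all genes they lay lower: after scaling Pkd1 passed at a log2 fold change of -0.31 (adjusted p = 0.0427), with Pkd2 at -0.44 (adjusted p = 0.0764) and Pkhd1 at -0.07 (adjusted p = 0.835). With quantile normalization Pkd1 stood at -0.41 (limma adjusted p = 0.0136). The authors' DESeq2 result gave -0.38 for Pkd1 (q = 0.00952). Pkd2 and Pkhd1 passed in neither, with a q of 0.0587 and 0.786 from DESeq2. Bicc1, an RNA-binding protein whose loss gives cysts in mice, rose 2.24-fold and Nek8, a ciliary kinase, 1.94-fold in mean FPKM, and the call of Nek8 ended with quantile normalization (adjusted p = 0.0565). Of 21 measured genes of cystic disease and the cilium 8 rose and 0 fell, and adjusted over the list alone 6 rose. With 1 library left out, 4 to 7 rose. The list did not pass (camera adjusted p = 0.486; adjusted p = 0.692 with an estimated correlation), and after scaling 3 rose and 3 fell.

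Control lists were read for other tissue, blood, handling and sex. The 4 measured red blood cell genes fell, with the same count adjusted over the list alone, and 2 of 3 measured fell without wild-type replicate 1 or without wild-type replicate 2 (camera adjusted p = 0.0064; adjusted p = 0.45 with an estimated correlation), and Hba-a1 stood at 798.3, 178 and 398.9 FPKM in wild type and at 37.5, 23.7 and 50.5 FPKM in NICD2_Pax8. Of 6 measured fat genes 0 passed by limma, with 1 under an unadjusted p of 0.05, although the set passed (camera adjusted p = 0.0213; adjusted p = 0.455 with an estimated correlation). After scaling 1 fat gene, Fabp4, fell, and without wild-type replicate 3 all 6 fell, with a median log2 fold change of -3.74. Of the 7 adrenal genes 1, Star, was measured; 0 passed by limma, with 0 under an unadjusted p of 0.05 (camera adjusted p = 0.38; adjusted p = 0.455 with an estimated correlation). Of 8 immediate early genes 6 rose and 1 fell, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.12; adjusted p = 0.455 with an estimated correlation). Their median log2 fold change was 2.36. Egr1 rose 14-fold, Atf3 10.4-fold and Fos 7.9-fold in mean FPKM, while Dusp1 fell 2.5-fold. Ier3, the most abundant, did not pass and stood at 35.1 ± 8.28 and 53.5 ± 15.1 FPKM (SD, n = 3 each). Whether handling differed between the groups was not tested. Y-linked transcripts were read in all 6 libraries: Eif2s3y stood at 35.5, 35.3 and 33.5 FPKM in wild type and at 28.3, 7.05 and 23.1 FPKM in NICD2_Pax8, and 0 of 4 measured sex chromosome genes passed by limma, with 1 under an unadjusted p of 0.05 (camera adjusted p = 0.148; adjusted p = 0.455 with an estimated correlation). After scaling 3 of these 4 fell, as did 3 without NICD2_Pax8 replicate 1. All 7 male-biased kidney genes fell, also adjusted over the list alone (camera adjusted p = 7.7e-05; adjusted p = 0.45 with an estimated correlation), with Slco1a1 at 39.8 to 50.3 FPKM in wild type and at 0, 2 and 0 FPKM in NICD2_Pax8. Of 5 female-biased genes 3 fell, among them Acsm3, 4.79-fold, and 1 rose, with the same counts adjusted over the list alone and 0 rising after scaling (camera adjusted p = 0.0213; adjusted p = 0.45 with an estimated correlation).

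A fold change on the log2(FPKM + 1) scale understates the change of genes near or under 1 FPKM. Camera with a preset correlation passed 14 of the 20 study lists, 0 passed with an estimated correlation (0 also at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, passed 18.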

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

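Settings named as added were chosen after seeing the data. Counts of calls stayed within 1.5 times of 8285 under the other pseudocounts, no filter, quantile, median-of-ratios and upper quartile scaling, and an adjusted p of 0.01. Leaving out 1 library gave 6454 to 8706 calls, with 4604 to 6644 higher and 1625 to 2062 lower. No gene called in both had the opposite direction in any setting that was run. Genes higher numbered 3982 with quantile normalization, 3873 with median-of-ratios and 3993 with upper quartile scaling, and genes lower 3419, 3473 and 3387; median-of-ratios scaling without wild-type replicate 1, added, gave 3600 lower. These scalings set the typical gene to about no change, which moves genes from the higher to the lower side. The added filter of 10 FPKM gave 5181 calls, 3742 higher and 1439 lower, from 7559 genes tested. Requiring a log2 fold change of at least 1 left 3436, 2427 higher and 1009 lower. With the replicate number as a block 7982 genes passed. Deviations of same-numbered libraries correlated at 0.0951, -0.0498 and 0.0056, and only replicate 1 correlated best with its own number. With 3 libraries per group these values cannot exclude a shared batch. The authors' pair columns compare same-numbered libraries, so whether the numbers pair the samples is not settled.

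Of the 14 lists that passed, 0 did with an estimated correlation. With the added filter of 10 FPKM the macrophage list no longer passed and the list of Notch receptors did. With fry 3 further lists passed in the same direction, and the principal cell list turned from down to up (adjusted p = 0.00741); the cause was not tested. Pkhd1 turned to -0.35 (adjusted p = 0.0233) with the added scaling without wild-type replicate 1; it did not pass in the other settings run, and the cause was not tested. The DESeq2 Wald test, limma-voom and the filter of 10 CPM need counts and were not run, and each symbol had 1 row, so testing rows on their own gave no value. An estimated 14800000 to 17900000 fragments per library limits genes near 1 FPKM.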

Other observations

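Pathways of the authors' annotation were read beside the lists. At the preset correlation 20 of 228 pathways passed upward and 74 downward, and 0 passed with an estimated correlation (camera; lowest adjusted p = 0.495; 20 at an unadjusted p under 0.05). DNA replication had 48 of 63 genes higher and 2 lower, and mismatch repair 22 of 27 higher and 0 lower. The spliceosome had 155 of 228 genes higher and the ribosome 131 of 204. Antigen processing and presentation had 78 of 119 higher and 8 lower. Peroxisome had 57 of 99 genes lower and 9 higher, degradation of valine, leucine and isoleucine 45 of 61 lower, and butanoate metabolism 21 of 30 lower. Collecting duct acid secretion had 18 of 31 lower and 3 higher. Some pathways close to the study lists gave other results at the preset correlation. Notch signaling (camera adjusted p = 0.519), ECM-receptor interaction (0.794), cytokine-cytokine receptor interaction (0.135) and chemokine signaling (0.611) did not pass. TNF and NF-kappa B signaling passed upward (0.00884 and 0.0106), and glycolysis and gluconeogenesis passed downward (0.00113). Of 646 tested genes that the file names as unannotated models, 232 were higher and 99 lower.

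The tests of adrenal tissue, of fewer proximal tubule cells and of dilution were chosen only after the results were seen. Wild-type replicate 1 held adrenal and fat transcripts. All 7 adrenal list genes reached at least 10 times their highest value in the other 5 libraries, so adrenal tissue taken with that kidney is a candidate source. The library did not set the number of calls, which was 8706 without it. No biological explanation of the adrenal transcripts was tested, because the design names none within the wild-type group.

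The fall of proximal tubule transcripts has several candidate explanations. After median-of-ratios scaling 21 of 22 markers passed, and their median log2 fold change went from -2.67 to -3.02. The factors of this scaling were 0.826 to 0.966 in wild type and 1.12 to 1.16 in NICD2_Pax8. It could therefore only enlarge a fall, so passing it is no test of scaling as a cause. The values show only that this correction does not remove the fall. Dilution by another cell type alone is argued against because the proximal tubule median lay 1.60 log2 units below the nearer of the podocyte and endothelial medians (difference -1.60). An even loss of proximal tubule cells alone would lower markers confined to these cells by the same amount. The interquartile range of the marker changes was 8.18 times their median standard error. This cannot decide the question, because markers also expressed in other cells would fall unevenly under an even loss. An even loss with shared markers, loss of particular segments, lower expression per cell in the NICD2_Pax8 genotype, and mixtures of these stay open and may act together.

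Of 14 measured transcripts abundant in liver 4 rose and 5 fell in NICD2_Pax8 kidneys, so they did not move as a group, and the genes named here were chosen after their values were seen. Gc, the vitamin D binding protein, went from 28.7 ± 12.1 to 1257 ± 2.83 FPKM (SD, n = 3 each; limma adjusted p = 4.68e-05), and Fgb from 0.99 to 46.2, Fgg from 3.13 to 25.6 and Ambp from 0.867 to 7.41 FPKM in the means, while Ttr went from 152.5 to 6.91 and Alb from 2.12 to 0.02 FPKM. Liver tissue as the source of the rise of Gc is argued against, because Alb was at most 4.77e-05 times Gc in the NICD2_Pax8 libraries. A change of expression in the kidney with the genotype may remain as a hypothesis that was not tested further.

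The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 8285 genes, 1 of the 10 splits gave as many, and the highest of the others gave 4.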
